A study of Mus musculus with 24 samples.

How the data were processed

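Libraries were made from messenger RNA of flow-sorted cells with a KAPA kit and sequenced on a NovaSeq, per the labels' protocols. Bowtie2, DESeq2 and Partek are named without versions in the submitters' processing notes, with the mouse build mm10. The annotation, the counting step, the filters and the model formula were not given in the sources used here. The files used were 3 tables of the authors' own comparisons of mutant with control, 1 per cell type and stage, and values per library were not analysed here. Per the file headers, each deposited table gives for each gene the authors' p-value, a step-up FDR, the ratio of mutant to control, a signed fold change and 1 least-squares mean per group. The deposited ratio equals the quotient of the authors' group means. The authors' group means were read as a signal, the mean normalized read count, whose scale factor is not stated, so the depth per library is unknown and no counting interval could be given.

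The tables list 21860, 23792 and 20523 genes for E11.5 pericytes, E13.5 pericytes and E13.5 endothelial cells. The deposited FDR was recomputed as the Benjamini-Hochberg value over the 19301, 20084 and 18132 genes that have one, and the genes without one lie at low mean levels. No value was given for 16, 17 and 3 genes. Genes with a deposited FDR under 0.05 are those called changed. The authors' deposited FDR is printed as the adjusted p throughout, taken as an adjusted p from DESeq2, and a gene list's adjusted p comes from limma. Every log2 ratio is the log2 of the deposited ratio.

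The plan made before the data were examined foresaw tests on values per library, with the authors' values as the fallback, and the fallback applied. The SE of a log2 ratio was obtained by dividing it by the normal deviate of the authors' two-sided p, which assumes a Wald test. No SE lay below the limit that Poisson counting would set for the deposited means. Differences between stages or cell types were tested with the difference of 2 log2 ratios over the root of their summed squared SE, with Benjamini-Hochberg adjustment, in place of the planned joint fit. Calls were compared between tables with Fisher's exact test, two-sided. The comparisons share no libraries. p-values measure only the spread between these samples, and nothing in the labels says whether samples came from separate litters.

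A set of 39 gene lists, 25 of pathways and 14 of cell type markers, with 854 distinct genes, was fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by cameraPR of limma 3.58.1 in R 4.3.3 on the signed normal deviates, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. A correlation estimated from the libraries, and fry, need values per library and were not run. A preset correlation of 0.05, ranks, and 10000 random lists matched on mean level in 20 bins were used beside it. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions come from GENCODE's annotation of the mm10 assembly, in which 97.5% of the tested gene symbols of each table were found.

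Genes were named by a rule set before the data were examined. It takes Tgfbr1, the 6 largest log2 ratios in each direction among called genes with a mean level above the median, up to 3 called members with the smallest p in each list that has at least 2 called members or passes its test, up to 6 genes called in both comparisons of a pair and 4 genes with the smallest p for each tested difference. Predicted genes, pseudogenes, Y-linked genes and Xist were left out of the largest ratios, and Timp3, Pdgfrb, Gucy1a1 and Gucy1b1 were always given in pericytes. A part of the rule that asks for no overlap between libraries could not be applied. Not every gene that the rule takes is printed, and Lin28a, Ccn2, Fth1, Tfrc, Hbb-bs, Xist, Eif2s3x and Kdm6a were named after their values were seen.

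The steps were tested on simulated data. Estimates were drawn with the implied SE and tested with that same SE, so the simulation does not check the SE itself. For E11.5 pericytes, 61% of 100 genes changed by 1 on the log2 scale and 94% of those changed by 2 were recovered among 19301 genes. The shares were 78% and 98% for E13.5 pericytes (20084 genes) and 73% and 88% for E13.5 endothelial cells (18132 genes). The difference between stages recovered 59.4% and 87.0%, and the difference between cell types 65.9% and 87.9%. Unchanged genes called numbered 6, 9 and 6 in these comparisons, and 11 and 13 for the differences between stages and between cell types. The alternatives tried were no filter on low genes, a log2 ratio of at least 1, and an FDR of 0.1 for the overlaps. Added after the data were seen were scaling to the summed means, rescaling the spread so that the median test statistic matches a standard normal, leaving out X-linked genes, and the list settings above.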

Results

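Messenger RNA was sequenced from cells sorted out of mouse embryonic brains, in 24 libraries. The mice carried Cre recombinase under control of Pdgfrb, a gene of pericytes and other mural and mesenchymal cells, together with a ZsGreen reporter. Controls carried 1 floxed copy of Alk5 and mutants carried 2. Alk5 is the older name of Tgfbr1, which encodes the type I receptor for TGF-beta, and the labels mark the mutants as having GMH-IVH. Pericytes were taken at E11.5 from 4 control and 4 mutant samples and at E13.5 from 4 control and 4 mutant samples, and endothelial cells at E13.5 from 5 control and 3 mutant samples. The stated purpose was to learn which pericyte genes depend on ALK5 during the growth of brain vessels. For each of the 3 comparisons the values used here were the authors' group means of normalized counts, their ratio and the authors' p, so read depth and spread per library were not analysed here. Standard errors (SE) below are those that the authors' ratio and p imply together.

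Among control cells, 18 pericyte markers with a value in the endothelial table had a median level of 140.4 and 20 endothelial markers one of 8875, at the 38.3rd and 98.5th percentile of gene levels in the authors' deposited table. The E13.5 control pericytes had a median of 1369 over 20 pericyte markers and 110.5 over 16 endothelial markers, at the 82.1st and 41.2nd percentile in the authors' deposited table. Markers of fibroblasts and meninges stood at the 96.7th percentile in the E13.5 pericytes and at the 89.8th in the E11.5 pericytes, and markers of cartilage and bone progenitors at the 91.5th and 65.9th, by control levels in the authors' deposited tables. The tables were normalized separately, so these levels were ranked within each table.

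Tgfbr1 spans positions 47353222 to 47414931 on the plus strand of chromosome 4 (mm10). Its level over the whole gene did not differ past the threshold in any comparison: in the authors' deposited tables the log2 ratio of mutant to control was 0.43 (SE 0.27, adjusted p = 0.399) in E11.5 pericytes, 0.03 (SE 0.08, adjusted p = 1.00) in E13.5 pericytes and -0.11 (SE 0.23, adjusted p = 0.859) in E13.5 endothelial cells. Reads over the deleted exons were not analysed here, so this level only partly checks the labels.

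At E11.5, mutant pericytes had less RNA of matrix and TGF-beta family genes and more of Sall4, Trim71 and Kitl. Sall4, a transcription factor of pluripotent and early embryonic cells, rose 4.30-fold, the RNA-binding regulator Trim71 2.41-fold and Kitl, the ligand of the KIT receptor, 3.70-fold in the authors' deposited table. Runx2, a transcription factor of bone progenitors, had a log2 ratio of -3.79 (SE 0.79), and Inhba, which encodes an activin subunit, one of -2.94 (SE 0.55) in the authors' deposited table. In all, 646 of 19301 genes passed an adjusted p of 0.05 in the authors' deposited table, 124 higher and 522 lower in mutants. Lin28a, an RNA-binding protein of early embryonic cells, was chosen after its values were seen and lies outside the naming rule, and it rose from a mean of 59.4 to 389 with an adjusted p of 1.3e-06 in the authors' deposited table.

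**Figure D1:**
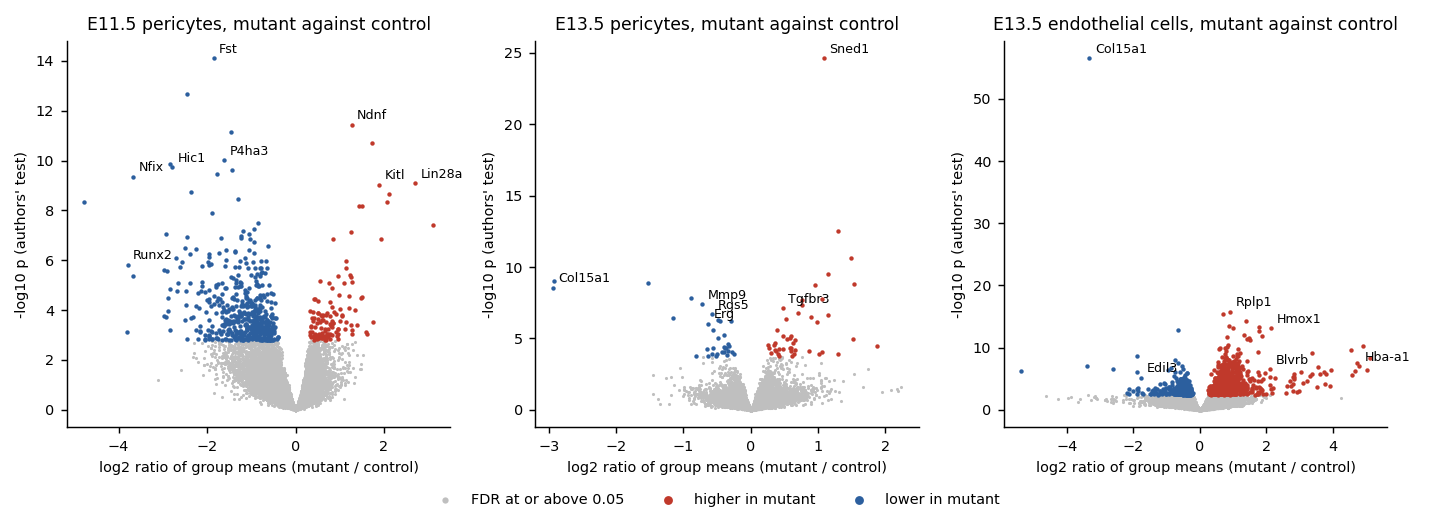
Each point is a gene with an adjusted p, placed by its log2 ratio of mutant to control and by the -log10 of the authors' p, for E11.5 pericytes, E13.5 pericytes and E13.5 endothelial cells; red and blue points are higher and lower in mutants at an adjusted p under 0.05. There are 646, 78 and 1323 such genes, Xist is left off every panel, and the vertical scales differ.

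Of 36 fibrillar matrix genes tested at E11.5, 12 fell and none rose, or 18 fell when adjusted over the list alone, with a median log2 ratio of -0.67 (limma's cameraPR, adjusted p = 2.29e-12). Among them the prolyl hydroxylase subunit P4ha3 fell 3.05-fold, the elastic fibre protein gene Eln 3.22-fold and the collagen gene Col6a2 1.77-fold, with adjusted p of 3.2e-07, 7.8e-05 and 0.0019 in the authors' deposited table. Of 22 TGF-beta ligands, receptors and partners other than Tgfbr1, 6 fell and none rose, or 8 fell when adjusted over the list alone (cameraPR, adjusted p = 6.06e-06). The activin antagonist Fst fell 3.60-fold and the ligand gene Tgfb1 3.91-fold, although the Tgfb1 means were only 34.8 and 8.91 in the authors' deposited table. Among 30 targets of TGF-beta signalling 4 fell and 1 rose, or 11 fell and 1 rose when adjusted over the list alone (cameraPR, adjusted p = 2.19e-05). Col1a2 and Postn were among those that fell, with log2 ratios of -0.69 and -0.96, and Ccn2, a matricellular protein gene, was the member that rose, with 0.74, in the authors' deposited table. Of 24 targets and antagonists of BMP signalling 6 fell, or 9 fell and 1 rose when adjusted over the list alone (cameraPR, adjusted p = 2.97e-05). Chrdl1, Nog and Grem1, which all encode BMP antagonists, had log2 ratios of -1.44, -1.35 and -2.68 in the authors' deposited table.

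Of 20 pericyte markers 5 fell at E11.5, or 7 when adjusted over the list alone (cameraPR, adjusted p = 7.52e-05). The G protein regulator gene Rgs5 fell 4.15-fold (adjusted p = 0.037), the ATP-sensitive potassium channel genes Kcnj8 and Abcc9 1.74-fold and 2.00-fold, and the proteoglycan gene Cspg4 1.98-fold in the authors' deposited table. Pdgfrb, Timp3, Gucy1a1 and Gucy1b1 had log2 ratios of 0.09, -0.10, -0.29 and -0.22 and adjusted p of 0.852, 0.836, 0.416 and 0.634 in the authors' deposited table. In the list of nitric oxide and cGMP genes 4 of 17 fell, or 5 when adjusted over the list alone (cameraPR, adjusted p = 0.00575), among them the phosphodiesterase genes Pde1c and Pde3a with log2 ratios of -0.75 and -0.68 in the authors' deposited table. Of 32 matrix protease genes and inhibitors 6 fell, or 7 when adjusted over the list alone (cameraPR, adjusted p = 4.85e-05), and Adamts5 and Mmp14 had log2 ratios of -1.28 and -0.89 in the authors' deposited table. Markers of other cells moved as well: of 20 myeloid markers 6 fell, or 16 when adjusted over the list alone, with a median log2 ratio of -1.04 (cameraPR, adjusted p = 8.88e-11). Of 14 endothelial markers 1 fell, or 7 when adjusted over the list alone, with a median log2 ratio of -0.92 (cameraPR, adjusted p = 4.22e-05). Erg was that marker, with a log2 ratio of -2.57, and the myeloid receptor gene Csf1r had one of -1.10 in the authors' deposited table.

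Of 16 markers of fibroblasts and meninges 4 fell and 1 rose at E11.5, or 7 fell and 1 rose when adjusted over the list alone, with a median log2 ratio of -0.70 (cameraPR, adjusted p = 0.00052). Col1a2, which is also in the lists of fibrillar matrix and TGF-beta targets, was among those that fell, as were the proteoglycan gene Ogn and the retinoic acid synthesis gene Aldh1a2, with log2 ratios of -1.08 and -2.11 in the authors' deposited table. The falls of matrix genes were therefore not separated from a fall of fibroblast markers. Of 6 markers of Schwann and neural crest cells 3 fell, or 5 when adjusted over the list alone, with a median of -1.21 (cameraPR, adjusted p = 5.27e-05). Of 11 markers of cartilage and bone progenitors 2 fell, Runx2 and Dlx5, also when adjusted over the list alone, with a median of -0.42 (cameraPR, adjusted p = 0.00568). Of 32 genes that respond to cell dissociation, a sign of sample handling, 3 fell, or 5 fell and 1 rose when adjusted over the list alone, with a median of -0.38 (cameraPR, adjusted p = 0.00447, and adjusted p = 0.0491 with a preset correlation of 0.05). Klf2 and Klf4, both transcription factor genes of that list, had log2 ratios of -1.96 and -1.75 in the authors' deposited table.

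In the opposite direction, 42 cell cycle genes had a median log2 ratio of 0.40 at E11.5 (cameraPR, adjusted p = 3.44e-12). The ribonucleotide reductase gene Rrm1 alone passed over all genes, at a ratio of 1.45 in the authors' deposited table, and 15 members rose when adjusted over the list alone. The 22 genes of cholesterol synthesis and uptake had a median log2 ratio of 0.38 (cameraPR, adjusted p = 4.83e-08), and 0 of them passed singly, over all genes or when adjusted over the list alone. Of 38 lists tested, 23 were lower and 4 higher. Genes in the lowest 25% of levels had a median log2 ratio of -0.23 and those in the highest 25% one of 0.10, so the ratios ran with the level. They also ran with transcript length, with medians of 0.07 for the shortest 25% of transcripts and -0.10 for the longest 25%. When the test statistics were rescaled so that their median matched chance, an alternative added after the data were seen that takes most genes as unchanged, 5 genes passed in place of 646.

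At E13.5, fewer genes differed in pericytes, among them Sned1, Col15a1, Lrrc32, Tgfbr3 and the vessel ligand genes Angpt1 and Angpt2. Sned1, which encodes a secreted matrix protein (chromosome 1, 93235841 to 93301065), rose 2.13-fold with an adjusted p of 4.8e-21 in the authors' deposited table. Lrrc32 and Tgfbr3, which encode a carrier of latent TGF-beta and a TGF-beta co-receptor, rose 1.69-fold and 1.39-fold in the authors' deposited table. Skil and Pmepa1, feedback genes of TGF-beta signalling, fell 1.49-fold and 1.27-fold, with adjusted p of 0.036 and 0.012 in the authors' deposited table. Col15a1, which encodes a basement membrane collagen, fell 7.67-fold, from a mean of 365 to 47.6, with a log2 ratio of -2.94 (SE 0.49, adjusted p = 5.8e-06) in the authors' deposited table. In all, 78 of 20084 genes passed, 45 higher and 33 lower in mutants. That there were fewer than at E11.5 depends on the spread: with it rescaled as above, 142 passed here and 5 at E11.5.

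Rgs5 fell 1.49-fold (adjusted p = 0.00022), the gelatinase gene Mmp9 1.65-fold and the transcription factor gene Erg 1.55-fold in E13.5 pericytes, by the authors' deposited table. Of 20 pericyte markers 1 fell, Rgs5, and 1 rose, Cox4i2, at 1.82-fold (adjusted p = 0.026) in the authors' deposited table. The counts were the same when adjusted over the list alone, the median log2 ratio was 0.10 and the list did not pass its test. The intermediate filament gene Des rose 2.09-fold and the integrin gene Itga4 1.44-fold in the authors' deposited table. Of 43 angiogenic ligands and receptors 3 rose and none fell, or 5 rose when adjusted over the list alone (cameraPR, adjusted p = 2.23e-05). They were Angpt1 and Angpt2, which encode opposing ligands of the endothelial receptor TIE2, at 1.30-fold and 1.49-fold, and the peptide gene Adm at 2.02-fold in the authors' deposited table. Angpt2 and Adm were also the 2 of 20 tip cell genes that rose, or 4 when adjusted over the list alone (cameraPR, adjusted p = 3.36e-07). The lists of integrins and adhesion proteins, contractile proteins and smooth muscle markers had median log2 ratios of 0.12, 0.16 and 0.38 (cameraPR, adjusted p = 3.52e-06, 2.23e-05 and 2.42e-05), each with 1 member past the threshold over all genes and 4, 3 and 2 when adjusted over the list alone. Des was the member in the latter 2. Of 25 basement membrane genes 1 fell, Col15a1, while the list as a whole had a median log2 ratio of 0.10 (cameraPR, adjusted p = 0.00075), and 3 rose and 1 fell when adjusted over the list alone.

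The lists of fibrillar matrix, matrix proteases, TGF-beta targets and TGF-beta components did not pass at E13.5. Of 32 TGF-beta targets 2 fell, or 3 when adjusted over the list alone (cameraPR, adjusted p = 0.0774), and of 23 TGF-beta ligands, receptors and partners 2 rose, or 3 rose and 1 fell when adjusted over the list alone (adjusted p = 0.227). Of 36 fibrillar matrix genes 1 fell, or 1 rose and 2 fell when adjusted over the list alone, and of 33 matrix protease genes 1 fell, also when adjusted over the list alone (cameraPR, adjusted p = 0.267 and 0.780). The 24 targets and antagonists of BMP signalling were lower, as at E11.5, with a median log2 ratio of -0.08 and 0 past the threshold, over all genes or when adjusted over the list alone (cameraPR, adjusted p = 0.0348, and adjusted p = 0.174 with a preset correlation of 0.05). Among 16 endothelial markers 14 had a positive log2 ratio, with a median of 0.24, while Erg alone passed and fell, also when adjusted over the list alone (cameraPR, adjusted p = 0.193, and adjusted p = 0.0175 by ranks). The 11 vein genes had a median log2 ratio of 0.14, with 0 past the threshold over all genes and 2 higher when adjusted over the list alone (cameraPR, adjusted p = 0.0143, and adjusted p = 0.0634 with a preset correlation of 0.05). The rise of the tip cell and angiogenic lists was therefore not separated from a rise of endothelial RNA in the sorted pericytes.

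Pdgfrb, Timp3, Gucy1a1 and Gucy1b1 had log2 ratios of 0.16, 0.07, 0.25 and 0.34 in E13.5 pericytes, with adjusted p of 1.00, 1.00, 1.00 and 0.313 in the authors' deposited table. Of 8 erythroid markers 0 passed singly, over all genes or when adjusted over the list alone, while their median log2 ratio was 2.02 (cameraPR, adjusted p = 5.14e-05). The haemoglobin genes Hba-a1 and Hbb-bs had log2 ratios of 2.08 and 2.17 in the authors' deposited table. Of 39 lists, 9 were higher and 3 lower. The 55 ribosomal protein genes were among the lower, with a median log2 ratio of -0.05 (cameraPR, adjusted p = 0.00095), and this call was lost with a preset correlation of 0.05 (adjusted p = 0.0702). The 33 genes that respond to cell dissociation were lower too, with a median log2 ratio of -0.28 and 0 past the threshold singly, over all genes or when adjusted over the list alone (cameraPR, adjusted p = 0.0143, and adjusted p = 0.143 with a preset correlation of 0.05). Xist, the RNA expressed from the inactive X chromosome and chosen after its values were seen, had means of 5.73 in mutants and 36145 in controls in the authors' deposited table. Xist is expressed in female cells and the sex of the samples was not given in the sources used here, so a difference in sex between these groups was not separated from genotype in the E13.5 pericyte calls or in the differences and overlaps that use them. The X-linked genes Eif2s3x and Kdm6a, which escape inactivation and were also chosen after their values were seen, had log2 ratios of -0.48 and -0.48 with adjusted p of 0.187 and 0.320 in the authors' deposited table. Of 814 X-linked genes tested 2 passed, against 0.405% of other genes (Fisher's exact test, two-sided, p = 0.773). Genes silenced on the inactive X need not differ by sex, so this count cannot speak against a difference in sex. Scaled to the summed means, 69.8% of the calls were higher in mutants in place of 57.7%.

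**Figure D2:**
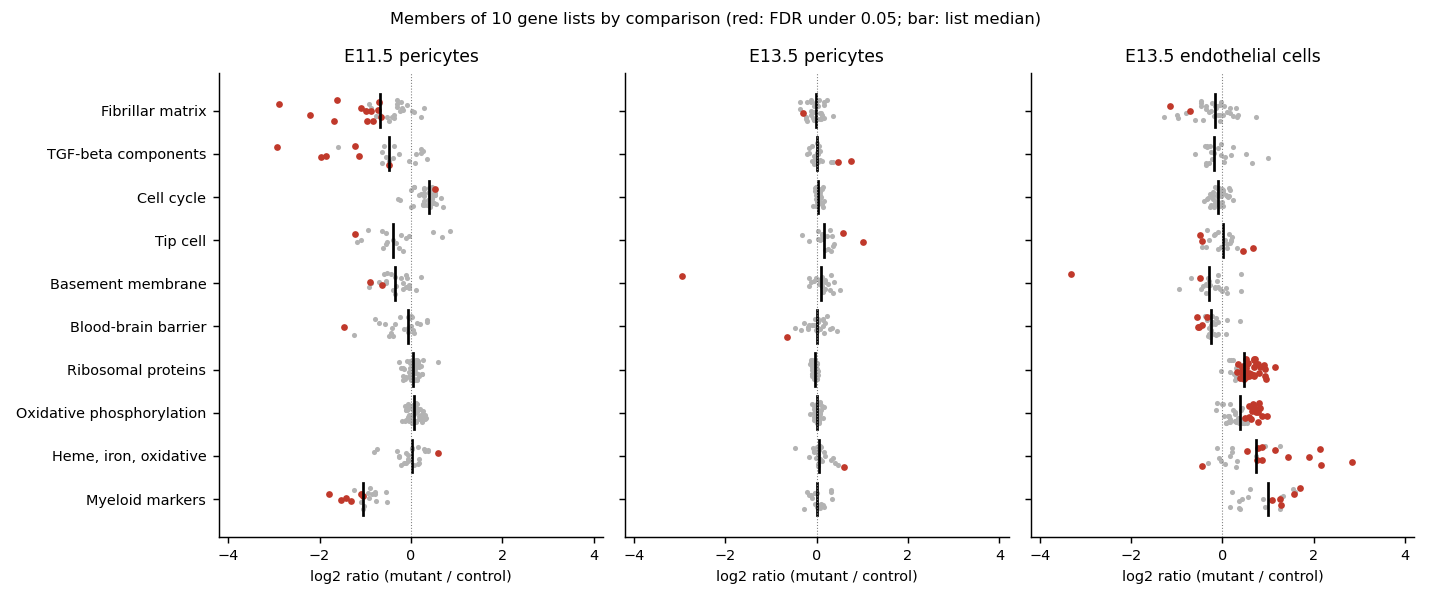
Each point is a member of 1 of 10 gene lists, placed by its log2 ratio of mutant to control in each comparison; red points have an adjusted p under 0.05, black bars are list medians and the vertical spread within a list carries no value. Fibrillar matrix members lie mostly below 0 at E11.5, with a median of -0.67, and ribosomal protein members above 0 in E13.5 endothelial cells, with a median of 0.48.

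In the E13.5 endothelial sort, genes of red cells, haem and iron, ribosomal proteins and respiration were higher in mutants. Col15a1 and several blood-brain barrier genes were lower. Hmox1, which encodes the haem-degrading enzyme haem oxygenase, rose 4.45-fold (log2 ratio 2.15, SE 0.29, adjusted p = 1.7e-10), and Blvrb, which encodes a biliverdin reductase, 4.37-fold in the authors' deposited table. The embryonic haemoglobin gene Hbb-y rose 33.0-fold and the alpha haemoglobin gene Hba-a1 27.8-fold, with log2 SE of 1.00 and 0.90, in the authors' deposited table. Col15a1 fell to a ratio of 0.0999, from a mean of 1196 to 120, with a log2 ratio of -3.32 (SE 0.21, adjusted p = 5.3e-53) in the authors' deposited table. In all, 1323 of 18132 genes passed, 926 higher and 397 lower in mutants.

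**Figure D3:**
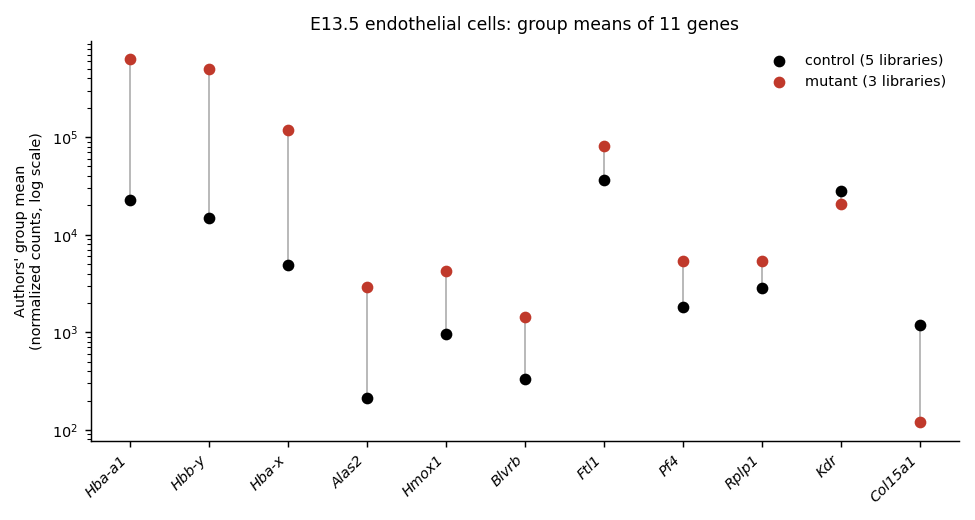
The authors' mean normalized count is shown on a log scale for 11 genes in E13.5 endothelial cells, with a black point for the mean of the control group (5 libraries) and a red point for the mean of the mutant group (3 libraries). Hba-a1 went from 22783 to 632622 and Col15a1 from 1196 to 120.

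Of 16 erythroid markers 12 rose and 1 fell, or 14 rose and 1 fell when adjusted over the list alone, with a median log2 ratio of 3.29 (cameraPR, adjusted p = 1.63e-14). The member that fell was the transferrin receptor gene Tfrc, with a log2 ratio of -0.44 in the authors' deposited table. Haemoglobin genes held 7.45% of the summed means in mutant and 0.302% in control endothelial cells, summed from the authors' deposited table. The rises of haem and iron, ribosomal, respiratory and interferon genes below were therefore not separated from RNA of red or myeloid cells in the sort. Of 25 haem, iron and oxidative stress genes 11 rose and 1 fell, or 13 rose and 2 fell when adjusted over the list alone (cameraPR, adjusted p = 4.06e-10), and the ferritin chain genes Ftl1 and Fth1 had log2 ratios of 1.14 and 1.44 in the authors' deposited table. Of 54 ribosomal protein genes 36 rose and none fell, or 45 rose when adjusted over the list alone, with a median log2 ratio of 0.48 (cameraPR, adjusted p = 1.99e-35). Rplp1 and Rplp2 rose 1.88-fold and 1.72-fold in the authors' deposited table. Of 46 respiratory chain genes 16 rose, or 25 when adjusted over the list alone (cameraPR, adjusted p = 1.4e-14), among them Ndufa6 and Cox8a at 1.71-fold and 1.66-fold in the authors' deposited table. Of 20 myeloid markers 5 rose, or 7 when adjusted over the list alone (cameraPR, adjusted p = 2.91e-05), and Pf4, Tyrobp and Aif1 had log2 ratios of 1.57, 1.25 and 1.69 in the authors' deposited table. Of 36 interferon and inflammation genes 4 rose, or 5 when adjusted over the list alone, with Ifitm1 at 2.03-fold in the authors' deposited table (cameraPR, adjusted p = 0.009, and adjusted p = 0.102 with a preset correlation of 0.05).

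Of 29 blood-brain barrier genes 5 fell and none rose, also when adjusted over the list alone, with a median log2 ratio of -0.26 (cameraPR, adjusted p = 2.25e-05). They included the amino acid transporter genes Slc7a1 and Slc7a5, at -0.52 and -0.35 on the log2 scale, and the tight junction gene Tjp1, at -0.53, in the authors' deposited table. Of 24 basement membrane genes 2 fell, or 4 when adjusted over the list alone (cameraPR, adjusted p = 7.11e-06), and Nid2 had a log2 ratio of -0.48 beside Col15a1 in the authors' deposited table. Among 20 endothelial markers the VEGF receptor gene Kdr fell 1.36-fold in the authors' deposited table, and 2 fell when adjusted over the list alone (cameraPR, adjusted p = 0.009, and adjusted p = 0.0659 with a preset correlation of 0.05). The integrin ligand gene Edil3 fell 3.39-fold, and the Wnt receptor genes Fzd4 and Fzd1 1.46-fold and 1.48-fold in the authors' deposited table. Median ratios ran with the length of the longest annotated transcript. Genes with the shortest 25% of transcripts had a median log2 ratio of 0.21 and those with the longest 25% one of -0.18. Ribosomal and respiratory genes are short. Of the barrier genes named, Slc7a1 and Tjp1 are long, at 7179 and 7049 nt, where the longest 25% start at 4371 nt, and Slc7a5 has 3517 nt. The falls of the barrier, basement membrane and endothelial lists were not compared with sets matched on length. They were therefore not separated from this trend. Nor were they separated from a larger share of other cells' RNA in the mutant sort, where erythroid and myeloid markers rose. The 20 endothelial markers had a median log2 ratio of -0.22, near the -0.26 of the barrier genes. The sum of all means was 0.13 higher in mutants on the log2 scale. Most of that difference came from haemoglobin genes, at 7.45% of the sum in mutants and 0.302% in controls. Scaled to that sum, 28.8% of 2199 calls were higher in place of 70.0% of 1323, so this setting depends largely on haemoglobin RNA. With the spread rescaled 49 genes passed.

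The change in mutants was compared between stages and between cell types from the ratios and their SE. Of 18267 genes, 262 differed between E11.5 and E13.5 pericytes, 246 of them with the more negative ratio at E11.5. The smallest p belonged to Fst, whose log2 ratio was -1.85 at E11.5 and 0.01 at E13.5, followed by Hic1 (-2.79 and 0.02), Adamtsl2 (-2.46 and -0.24) and Nfix (-3.67 and -0.07), in the authors' deposited tables. Hic1 and Nfix encode transcription factors. Of 16920 genes, 666 differed between E13.5 pericytes and endothelial cells, 499 of them with the more negative ratio in pericytes. The 4 genes with the smallest p were the mitochondrial gene mt-Nd3, at log2 ratios of -0.06 in pericytes and 1.00 in endothelial cells, the ribosomal protein genes Rps15a (-0.16 and 0.76) and Rplp1 (-0.05 and 0.91), and the predicted gene Gm10443 (-0.05 and 1.32), in the authors' deposited tables. The fall of Col15a1 did not differ past the threshold between the cell types, at 0.38 for pericytes minus endothelial cells with a 95% interval from -0.67 to 1.44. With the spread rescaled, 2 genes differed between stages and 15 between cell types. Scaled to the summed means, 445 differed between stages and 1224 between cell types. Of the latter 316 had the more negative ratio in pericytes and 908 the more positive, so that split turned around. In endothelial cells that scale rests largely on haemoglobin genes.

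E11.5 and E13.5 pericytes shared 16 of their called genes, against 2.59 for independent calls (Fisher's exact test, two-sided, p = 4.48e-09, adjusted over all 9 overlap tests 2.01e-08), and 15 of them went the same way. Eno3, Asic4, Wfdc1 and Des rose at both stages, with log2 ratios of 1.28, 1.20, 1.51 and 0.97 at E11.5 and 0.70, 1.52, 1.87 and 1.06 at E13.5, in the authors' deposited tables. Erg and Cpxm2 fell at both stages, with log2 ratios of -2.57 and -1.77 at E11.5 and -0.64 and -0.38 at E13.5, in the authors' deposited tables. E13.5 pericytes and endothelial cells shared 3 genes, against 4.45 for independent calls (Fisher's exact test, two-sided, p = 0.625, adjusted 0.704). These were Col15a1, the transporter gene Abcc4, with log2 ratios of -0.64 and -0.56, and Rasgrp2, with 0.65 and 0.56, in the authors' deposited tables. E11.5 pericytes and E13.5 endothelial cells shared 26 genes, fewer than the 39.8 of independent calls (Fisher's exact test, two-sided, p = 0.0189, adjusted 0.0425), and 16 went the same way. The deficit was not seen among genes lower in both, with 15 shared against 9.99 (Fisher's exact test, two-sided, p = 0.105, adjusted 0.155).

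**Figure D4:**
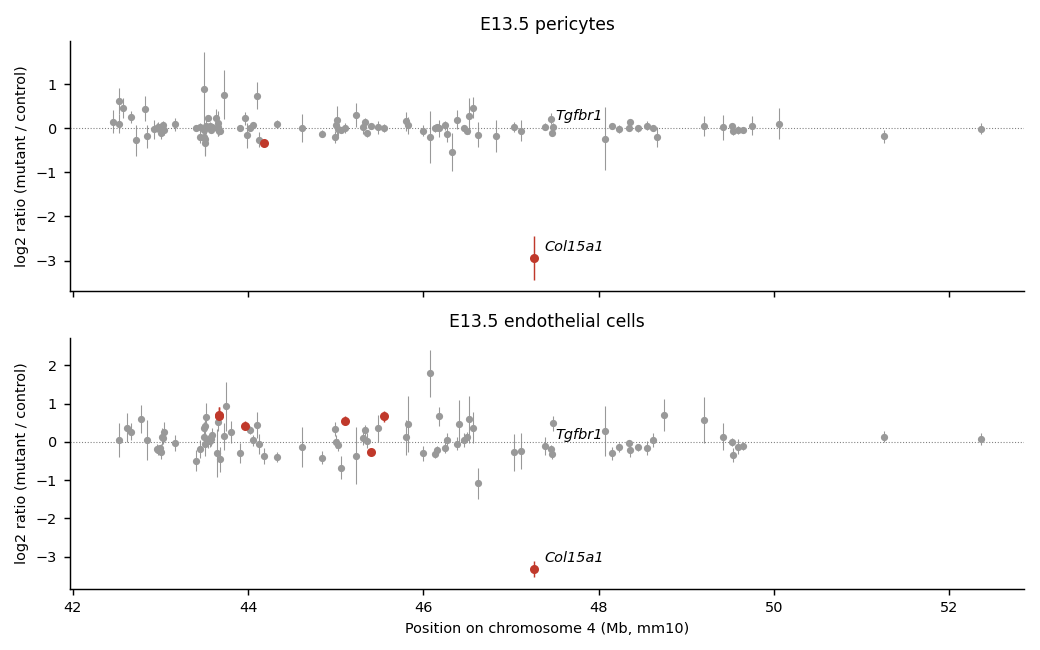
Each point is a gene within 5 Mb of Tgfbr1, placed by its position on chromosome 4 in Mb (mm10) and its log2 ratio of mutant to control in E13.5 pericytes (top) and endothelial cells (bottom); bars are 1 implied SE and red points have an adjusted p under 0.05. Col15a1, 40.1 kb before Tgfbr1, lies at -2.94 and -3.32.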

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

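The tests on RNA of red blood cells and on ALK5 acting within pericytes were chosen only after their results were seen. Tests for single libraries far from their group need values per library and were not run. Each difference given between stages or cell types in the next 2 paragraphs is between 2 log2 ratios of mutant to control and passed a test of that difference at an adjusted p under 0.05.

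Between E11.5 and E13.5 pericytes 262 genes and 27 of 37 gene lists differed. Among TGF-beta and BMP family genes the E11.5 ratio minus the E13.5 ratio was -1.86 for Fst, -2.96 for Inhba, -2.04 for Tgfb1, -1.22 for Nog and -2.39 for Grem1. For matrix genes it was -1.38 for P4ha3, -1.64 for Eln, -0.88 for Col6a2, -2.90 for Col8a1, -1.998 for Col14a1, -1.004 for Col4a6, -1.94 for Matn4, -1.26 for Ogn and -1.56 for Sned1. Matrix enzymes and adhesion genes gave -1.39 for Adamts5, -0.87 for Mmp14, -2.23 for Adamtsl2, -0.67 for Tns1 and -0.67 for Itga1. Transcription factor genes gave -2.81 for Hic1, -3.60 for Nfix, -3.61 for Runx2, -2.67 for Dlx5, -3.73 for Dlx6, -1.80 for Emx2, -1.64 for Klf4, -1.94 for Erg, -1.64 for Irf8 and -1.65 for Spi1. Signalling genes gave -1.60 for Penk, -2.96 for Calca, -1.16 for Vegfa, -0.53 for Slit3, -1.47 for Apcdd1 and -0.84 for Pde1c. Other genes gave -2.04 for Aldh1a2, -0.94 for Kcnj8, -1.19 for Cox4i2, -3.14 for Myh3 and -1.53 for Ly86. The difference was positive for Sall4 at 2.05, Nrsn1 at 1.67 and Ndnf at 0.95.

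Between E13.5 pericytes and endothelial cells 666 genes and 19 of 36 gene lists differed, or 6 lists with a preset correlation of 0.05. The pericyte ratio minus the endothelial ratio was -1.06 for mt-Nd3, -0.92 for Rps15a, -0.96 for Rplp1, -0.88 for Rplp2, -0.78 for Rps23 and -1.37 for Gm10443. Respiratory genes gave -0.84 for Ndufa6, -0.73 for Cox8a and -0.93 for Ndufa3, and haem and iron genes -1.99 for Hmox1, -2.06 for Blvrb and -1.11 for Ftl1. It was -1.79 for Pf4, -0.93 for Ackr3, -0.98 for Ifitm1 and -1.05 for Nfix. Some single matrix and adhesion genes went the other way, with 1.88 for Sned1, 1.82 for Edil3, 0.60 for Nid2, 0.66 for Bgn, 0.59 for Itga1 and 0.67 for Tns1. Positive differences were also found for Tgfbr3 at 1.08, Mpdz at 0.99, Slit2 at 0.85, Fzd4 at 0.73, Fzd1 at 0.62, Tjp1 at 0.55, Stk25 at 0.86, Trim71 at 1.45 and Wfdc1 at 1.84.

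Genes that fell in E11.5 mutant pericytes were mostly genes that are higher in controls at E13.5, while Sall4 and Trim71 rose. Low expression of the called genes is argued against, since 83.7% of the 515 genes called lower had the higher control mean at E13.5 once the median difference of all shared genes was set to 0, against 50.3% in sets of like level, with 95% of sets between 46.0% and 54.6%. Fewer endothelial and blood cells as the whole cause was tested among 7506 genes lower in endothelial cells than in pericytes. Each level was taken relative to the median of the shared genes in its table. Spearman's rho across these genes between the mutant change and the control difference E13.5 minus E11.5 was -0.343. This argues against that cause as the whole, unless a trend of the ratios with level gave it. Over 18267 genes that rho was -0.379, where noise in the shared control mean gave 0.117 on average and 0.133 at most in simulation, and this is consistent with an earlier developmental state of the mutant cells. Delayed maturation and younger mutant embryos stay open. So does a smaller share of fibroblasts or of cartilage and bone progenitors in the mutant sort, which was not tested. Their markers had median log2 ratios of -0.70 and -0.42 at E11.5. In control pericytes they stood at the 89.8th and 65.9th percentile at E11.5 and at the 96.7th and 91.5th at E13.5. The tables were normalized separately, and genes are not independent replicates.

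Ribosomal protein genes rose in E13.5 mutant endothelial cells, where ratios also ran with transcript length. A gain of short transcripts as the whole cause stays open. The median log2 ratio of 54 ribosomal protein genes was 0.48, against 0.18 in sets matched on length and level. Of those sets 95% lay between 0.12 and 0.27. Length was that of the longest annotated transcript, at 5179 nt for Rps15a and 499 nt for Rplp1. It need not be the transcript expressed, so the match on length may be poor and the test cannot decide. RNA of red blood cells and a change within endothelial cells cannot be told apart, because haemoglobin genes held 7.45% of the mutant and 0.302% of the control means and no profile of red cells was used here. Hba-a1 and Hbb-y were among the most abundant of them, and the endothelial sort would be meant to remove such cells.

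Col15a1 fell in E13.5 pericytes and endothelial cells and ends 40.1 kb before Tgfbr1. The test on its neighbours was reworded once its position and fall were known and before its result was. DNA linked to the floxed allele that changes several neighbours cannot be told apart from no such effect: the larger of 2 p-values was 1 (Fisher's exact test, two-sided), with 6 of 92 neighbours called in endothelial cells and 1 of 103 in pericytes, while at E11.5 it was 7 of 94 (p = 0.0403). Loss of ALK5 acting within pericytes stays open for the fall in pericytes. The pericyte ratio minus the endothelial ratio was 0.38 with a 95% interval from -0.67 to 1.44. Control levels argue against such loss as the whole cause of both falls by way of pericyte RNA in the endothelial sort. Whether mutant pericytes changed Col15a1 within endothelial cells was not tested. Col15a1 had a mean of 1196 in endothelial cells, where 18 pericyte markers had a median of 140.4. In pericytes it had a mean of 365, where 20 such markers had a median of 1369. Pericyte RNA in the endothelial sort would therefore explain little of the endothelial fall. A DNA difference at Col15a1 alone was considered and then left out, because Col15a1 had no value at E11.5 to test it with. It stays open: controls carried 1 floxed copy and mutants 2, and Col15a1 fell in both E13.5 fractions, at log2 ratios of -2.94 and -3.32.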

How the results depend on the processing

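Scaling to the summed means, rescaled spread, omission of X-linked genes and the other list settings were chosen after the data were seen. No paired analysis was possible because values per library were not analysed here. For the same reason edgeR and DESeq2 refits, other normalizations, pseudocounts, a fit of all libraries, leaving out single libraries and other splits of the samples were not run, so whether 1 library decides a call is not known. With a log2 ratio of at least 1, the calls went from 646 to 315 in E11.5 pericytes, from 78 to 17 in E13.5 pericytes and from 1323 to 247 in E13.5 endothelial cells, as a subset by construction. With the spread rescaled they were 5, 142 and 49, and the tested differences went from 262 to 2 between stages and from 666 to 15 between cell types, because the factors applied to the statistics were 1.51, 0.864 and 1.48. That rescaling takes most genes as unchanged, which was not tested. Scaling to the summed means gave 2199 calls in endothelial cells in place of 1323, with 1031 shared, and 445 and 1224 differences in place of 262 and 666, since it shifts every ratio of a table alike. The shift in endothelial cells came mostly from haemoglobin genes, at 7.45% of the summed means in mutants and 0.302% in controls. It left 817 and 86 calls in the pericytes. Without a filter on low genes the calls were 594, 73 and 1247, and without X-linked genes 622, 76 and 1262. Tgfbr1 stayed short of the threshold under each alternative run. A preset correlation of 0.05 left 7 of 12 lists in E13.5 pericytes and 8 of 15 in endothelial cells, and 20 of 27 at E11.5; ranks gave 14, 20 and 24. At 0.05, the lists that differed went from 27 to 22 between stages and from 19 to 6 between cell types, with 2 more positive and 4 more negative in pericytes in place of 12 and 7. Overlaps of genes called in either direction kept their direction and side of the threshold at an FDR of 0.1, with 24, 6 and 62 shared genes. The overlap of genes higher in E11.5 pericytes and in endothelial cells crossed it, from 1 shared gene (Fisher's exact test, two-sided, adjusted p = 0.081) to 2 where 16.2 would be shared by chance (adjusted p = 2.38e-05). No called list changed the sign of its median when scaled to the summed means.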
